A study of Mus musculus with 8 samples.

How the data were processed

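RNA sequencing of sorted mouse bone marrow LSK cells was analysed from 1 table of raw read counts per gene symbol, with 8 libraries, 4 from Hdc-GFPhi and 4 from Hdc-GFPlo cells. Per the labels' protocols, RNA was isolated from 2000 sorted cells per library, amplified with a SMARTer ultra-low-input kit and made into libraries with Nextera XT. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2, TopHat2 (version given as 2.04) and HTSeq 0.6.1 were used with the genome build mm9. The role and settings of each tool, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies cannot be told apart. No coordinates are printed. The counts were deposited as whole numbers per gene, not normalized, and each library has its own total (16726179 to 23051277). The table's columns carry library codes that the labels' descriptions tie to samples. GFP reads are not analysed here.

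Groups and replicate numbers come from the sample titles. Hdc-GFPhi replicate 4 has a cell type label with GFP+ where the other libraries of its group have GFPhi, and was kept in its titled group. No label says that replicates came from separate animals, so the p-values measure the spread between these samples, which may be in part technical. No 2 libraries of a fraction agreed within sampling noise. A chi-square per degree of freedom between pairs of libraries was at least 13.3, where about 1 would mean repeated sequencing of the same library.

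Genes were kept with edgeR's filterByExpr (13300 of 23284) and scaled by TMM. The main test was edgeR 4.0.16 quasi-likelihood (glmQLFit with robust estimation, glmQLFTest) of Hdc-GFPhi against Hdc-GFPlo with no covariate, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is said to be called, or to have risen or fallen, when it passed that threshold. Log2 fold changes are positive where Hdc-GFPhi is higher and are given ± SE with 95% intervals from the same fit. CPM values are TMM-scaled, with SD over 4 libraries. Per-library log2 CPM used a prior count of 2. The biological coefficient of variation was 19.9%. Intervals rest on the spread between libraries in that fit. The amplification carries no molecular identifiers, so reads copied from the same molecule are counted separately. In simulated Hdc-GFPhi and Hdc-GFPlo libraries (13156 genes tested), the test recovered 26.5% of genes changed by 0.5 on the log2 scale and 74.0% of those changed by 1. It recovered 87.8% at 2 and 100% at 4, with 3 calls among unchanged genes. The S phase list was also shifted by 0.5. Camera called it and 1 other list, which was not shifted as a whole but may hold shifted genes. Simulated genes were drawn independently of each other. The rate of false list calls therefore does not carry over to real lists, whose members can vary together.

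Gene lists (28, with at least 5 tested members) for histamine, stem cell, lymphoid, myeloid and other lineage programmes, cell cycle, stress and metabolism and for markers of other cell types were fixed before the data were examined. They were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. The median and mean of a list are over its tested members. Mean list levels per library were compared with an exact two-sided permutation test over the 70 assignments of 4 and 4 libraries. Lists share members, so their results are not independent.

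The named genes follow a rule fixed before the data were examined. Hdc and other tested histamine genes come first. Then come the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose mean raw count was at least 50, leaving out predicted genes. Last, up to 4 members of each list with the smallest p are named. A gene that this rule names and that does not appear is not used here. The T and NK cell genes too low to test, Fos, Egr1, the pancreatic enzyme genes and other genes without such a place were chosen after their values were seen.

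Alternatives listed before the data were examined were DESeq2 size factors, upper-quartile factors, no composition factor, no filter beyond 1 count, a filter of at least 50 counts in 4 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no robust estimation, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were removal of a per-library trend on GC content and transcript length, leaving out both libraries at the ends of the first 2 principal components, the split of replicates 1 and 2 against 3 and 4 as a covariate and each side of it alone, thinning of all libraries to the smallest total, and principal components under other scalings and filters. Lengths and GC content came from GENCODE M21 transcripts, matched by symbol or synonym for 97.9% of the genes and all tested list members. That annotation is on another build than mm9 and served for these 2 properties alone.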

Results

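RNA was sequenced from haematopoietic stem and progenitor cells of mouse bone marrow, taken as the LSK fraction, which lacks lineage markers and carries the surface proteins Sca-1 and c-Kit. The mice carried a green fluorescent protein reporter for histidine decarboxylase (Hdc), the enzyme that makes histamine. The LSK cells were sorted by GFP into a high fraction (Hdc-GFPhi, n = 4 libraries) and a low fraction (Hdc-GFPlo, n = 4 libraries), each library from 2000 cells. Raw read counts were available for 23284 genes, with totals of 21041170 to 22470121 counts per Hdc-GFPhi library and 16726179 to 23051277 per Hdc-GFPlo library, and 14856 to 15446 genes had at least 1 count in a library. The comparison asks how the transcriptomes of these progenitors differ with the activity of the Hdc reporter.

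Hdc-GFPhi cells had far less of the transcripts that mark early lymphoid and B lineage progenitors, and modestly more of several transcripts of haematopoietic stem cells. Dntt, which encodes the terminal transferase of early lymphocyte precursors, averaged 213 ± 73.9 CPM in Hdc-GFPhi and 1066 ± 196 CPM in Hdc-GFPlo (SD, n = 4 each), a 5.01-fold lower level. Esam, an adhesion protein of stem cells and endothelium, averaged 108 ± 19.2 against 58.4 ± 12.7 CPM, a 1.84-fold higher level (adjusted p = 0.0253, lost without Hdc-GFPhi replicates 1, 2 or 3 or Hdc-GFPlo replicates 1 or 4, with adjusted p up to 0.0929). Markers of myeloid progenitors, monocytes and dendritic cells were also lower in Hdc-GFPhi. The Hdc transcript itself averaged 12 CPM in Hdc-GFPhi and 12.1 CPM in Hdc-GFPlo. Of 13300 genes tested with edgeR, 126 passed an adjusted p of 0.05, of which 94 were lower and 32 were higher in Hdc-GFPhi, and 1449 had an unadjusted p under that value. The difference was at least 2-fold for 60 of the lower and 9 of the higher genes. In all 126 genes, the 4 libraries of each fraction did not overlap. This separation was seen for 6.92% of all tested genes, where chance gives 2.86%.

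The genes that fell most in Hdc-GFPhi included Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B cell receptor, and Il7r, the receptor for the lymphoid cytokine IL-7. The log2 fold change was -4.34 ± 0.74 (SE) for Igll1 (adjusted p = 0.0483), -3.87 ± 0.38 for Vpreb1 (adjusted p = 3.7e-04) and -2.73 ± 0.25 for Il7r (adjusted p = 3.7e-04). Vpreb1 has a near-identical copy, Vpreb2, which was also lower (log2 fold change -4.28), and the treatment of reads shared by both is not given in the sources used here. The transcription factors Tcf7 and Lef1, effectors of Wnt signalling in lymphocyte development, had log2 fold changes of -3.38 and -3.74. Gfra2, a receptor for neurturin, Colq, the collagen-like anchor of acetylcholinesterase, and Cox6a2, a muscle-type subunit of cytochrome c oxidase, had log2 fold changes of -4.24, -3.65 and -2.85. In Hdc-GFPhi, Gfra2, Colq, Cox6a2, Tcf7 and Lef1 averaged 0.572, 0.386, 0.63, 0.821 and 0.963 CPM. At such low levels the size of a fall is less certain than its direction. The call on Igll1 was lost when any library other than Hdc-GFPhi replicate 4 was left out, with adjusted p values of up to 0.151. The Lef1 call was lost without Hdc-GFPhi replicate 2 or 3 or Hdc-GFPlo replicate 1, 3 or 4 (adjusted p up to 0.0851), and the Colq call without Hdc-GFPhi replicate 3 or Hdc-GFPlo replicate 1 (up to 0.0763). Igll1 also missed the threshold under the other scalings (adjusted p = 0.0512 to 0.055), with no filter (0.0978) and with the GC and length trend removed (0.0518). Lef1 missed it with no filter (0.0703), and Tcf7 with voom (0.101) and without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together (0.0616).

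The genes that rose most in Hdc-GFPhi changed by smaller factors. The kinesin Kif21a rose 2.73-fold (log2 fold change 1.45 ± 0.23, adjusted p = 0.0086), the actin-bundling protein Fscn1 rose 2.58-fold (1.37 ± 0.20, adjusted p = 0.00599) and the ephrin receptor Ephb4 rose 2.30-fold (1.20 ± 0.17, adjusted p = 0.00506). The luteinizing hormone receptor Lhcgr, the Ikaros family factor Ikzf4, Fam115a, the caveolar protein Prkcdbp and the basement membrane collagen Col4a1 had log2 fold changes of 1.28, 1.24, 1.12, 1.04 and 1.03. These 5 calls were each lost in some fits with 1 library left out. Lhcgr reached an adjusted p of 0.0698 without Hdc-GFPlo replicate 1 or 4, and Col4a1 reached 0.0536 without Hdc-GFPhi replicate 3 or Hdc-GFPlo replicate 1. Fam115a was lost without Hdc-GFPhi replicates 1, 2 or 3 or Hdc-GFPlo replicates 1 or 2 (up to 0.0998). Ikzf4 was lost in 6 of 8 such fits, all but those without Hdc-GFPhi replicates 2 or 4 (up to 0.117), and Prkcdbp in 6, all but those without Hdc-GFPhi replicate 2 or Hdc-GFPlo replicate 3 (up to 0.0816). Without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together, Lhcgr (0.0611) and Ikzf4 (0.0761) were lost, and Fam115a was lost after thinning to the smallest library (0.0533).

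**Figure D1:**
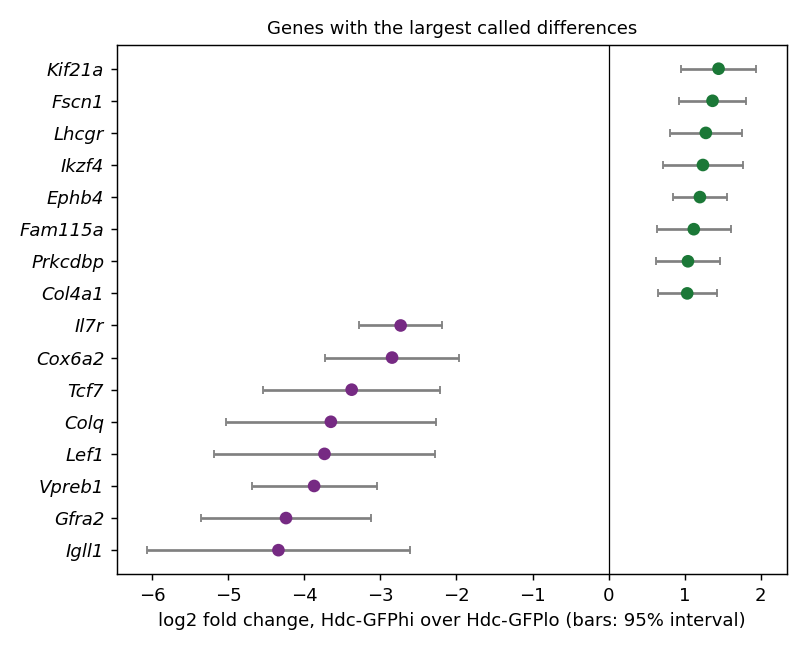
Log2 fold changes of Hdc-GFPhi over Hdc-GFPlo on the x axis for the 8 genes with the largest called rise and the 8 with the largest called fall, 1 gene per line. Points are estimates from 4 libraries per group and bars are 95% intervals; the falls reach -4.34 (Igll1) while the largest rise is 1.45 (Kif21a).

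Genes of lymphoid priming, which mark the first steps of multipotent progenitors towards lymphocytes, were lower in Hdc-GFPhi as a list. Of 22 measured genes, 12 were called lower and none higher, while adjusted over the list alone 18 were lower and 1 was higher. The list median was -0.74 on the log2 scale (camera adjusted p = 1.9e-45, and adjusted p = 0.0195 with an estimated correlation). Beside Dntt (log2 fold change -2.32 ± 0.21), the recombinase gene Rag2 (-2.13 ± 0.23) and Cnn3, an actin-binding protein (-1.44 ± 0.14), were called with adjusted p values of 3.7e-04 for Dntt and Cnn3 and 9.6e-04 for Rag2. Called lymphoid genes numbered 7 without Hdc-GFPhi replicate 1 and 7 without Hdc-GFPlo replicate 1. B cell genes were also lower as a list, with 7 of 18 called lower, 11 lower when adjusted over the list alone and a median of -1.71 (camera adjusted p = 2.4e-28, and adjusted p = 0.0429 with an estimated correlation). Among them, Ebf1, the transcription factor that specifies the B lineage, fell by 2.42 ± 0.35 (adjusted p = 0.00533), and Cd79a, a signalling chain of the B cell receptor, fell by 2.15 ± 0.30 (adjusted p = 0.00507). The B cell and lymphoid lists share Igll1 and Rag1. Dendritic cell genes were lower as a list, with 4 of 13 called lower, 9 lower when adjusted over the list alone and a median of -0.83 (camera adjusted p = 1.5e-17, and adjusted p = 0.0285 with an estimated correlation). They included the chemokine receptor Ccr9, which guides cells to thymus and gut and fell by 2.25 ± 0.34, and Ly6d, a surface marker of lymphoid precursors, which fell by 1.57 ± 0.25. Both calls were lost without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together (adjusted p = 0.0817 for Ccr9 and 0.056 for Ly6d). Of the called dendritic cell genes, Ccr9 is also in the lymphoid list, Irf8 in the myeloid progenitor list and Cox6a2 in the oxidative phosphorylation list. Only Ly6d is in no other list, so these calls are largely not separate from those of other lists. With the split of replicates 1 and 2 against 3 and 4 described below as a covariate, 11 B cell genes were called lower, and DESeq2 called 11 B cell and 7 dendritic cell genes.

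Genes of myeloid differentiation were lower in Hdc-GFPhi as lists. Of 25 myeloid progenitor genes, 3 were called lower and none higher (7 lower when adjusted over the list alone), with a median of -0.23 (camera adjusted p = 9.2e-08, and adjusted p = 0.0285 with an estimated correlation). These were Irf8, the transcription factor of monocyte and dendritic cell fate (log2 fold change -1.29 ± 0.18, adjusted p = 0.00507), Cst7, a cysteine protease inhibitor of granules (-1.36 ± 0.22, adjusted p = 0.00891), and Anxa3, an annexin of granulocytes (-0.91 ± 0.17, adjusted p = 0.0229). Of 20 monocyte and macrophage genes, 3 fell (9 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.1e-06, and adjusted p = 0.0285 with an estimated correlation). These were the lectin receptor Clec12a (-1.64 ± 0.24), the monocyte surface protein Ly6c2 (-1.17 ± 0.18) and the chemokine receptor Ccr2 (-1.36 ± 0.26). Anxa3 lost its call without Hdc-GFPhi replicates 2 or 3 or Hdc-GFPlo replicates 1, 2 or 3 (adjusted p up to 0.0886), and Ccr2 in all fits with 1 library left out except those without Hdc-GFPhi replicate 2 or Hdc-GFPlo replicate 3 (up to 0.112). Cst7 lost its call without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together (adjusted p = 0.0591). The 3 called myeloid progenitor genes became 5 with the GC and length trend removed, 6 with the split of replicates as a covariate, 6 with DESeq2 and 5 with voom. The 3 monocyte genes became 7 with the covariate and 6 with DESeq2. None of 18 mature neutrophil genes was called, and 17 had a log2 fold change below 0 (median -0.45, camera adjusted p = 2.2e-06, but adjusted p = 0.144 with an estimated correlation).

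Markers of T, NK and plasma cells were uneven in level. Of 10 measured T and NK cell genes, the kinase Lck, which is also in the lymphoid list, fell by 0.59 ± 0.10 (adjusted p = 0.018) and none rose, with 5 lower when adjusted over the list alone and a median of -0.68 (camera adjusted p = 3.8e-07, but adjusted p = 0.133 with an estimated correlation). Lck lost its call without Hdc-GFPhi replicates 1, 3 or 4 or Hdc-GFPlo replicate 1 (adjusted p up to 0.0867). With the split of replicates 1 and 2 against 3 and 4 as a covariate, the members Klrd1 and Cd247 were also called lower. Their adjusted p was then 0.0355 and 0.0405, against 0.0748 and 0.142 in the main fit. Further members had too few counts to be tested, among them the T cell receptor subunit genes Cd3e, with 0 counts in all Hdc-GFPhi libraries together and 7 in all Hdc-GFPlo libraries, and Cd3g, with 5 and 14. The kinase Zap70 had 20 and 68 counts, the granzyme Gzma 15 and 52, Trat1 10 and 38, Klre1 4 and 18, Ncr1 4 and 13 and Eomes 3 and 7. Cd3d had 26 and 13 and the transcription factor Tbx21 19 and 8, and Cd8b1 had 0 and 3 and Cd8a none. None of 6 plasma cell genes was called (4 lower when adjusted over the list alone, median -0.86, camera adjusted p = 4.1e-04, but adjusted p = 0.0717 with an estimated correlation). Igj, the joining chain of secreted antibodies, had 9 to 13 counts in the Hdc-GFPhi libraries, 18 in Hdc-GFPlo replicate 1 and 1604 to 3313 in the other Hdc-GFPlo libraries (adjusted p = 0.119, but 4.5e-08 without Hdc-GFPlo replicate 1, 0.00697 without robust estimation and 2.3e-09 with DESeq2). With the replicate number as a block the adjusted p of Igj was 0.00305, and with the split as a covariate it was 0.123. The plasma cell gene Sdc1 was called lower with that covariate (adjusted p = 0.0474). Sdc1 and Irf4 did not share the gap of Igj between Hdc-GFPlo replicate 1 and the other Hdc-GFPlo libraries. In log2 CPM, Sdc1 was at 5.14 against 4.75 to 5.04 and Irf4 at 3.62 against 3.13 to 3.83. Derl3 was lower in Hdc-GFPlo replicate 1, at 0.72 against 1.02 to 1.63.

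**Figure D2:**
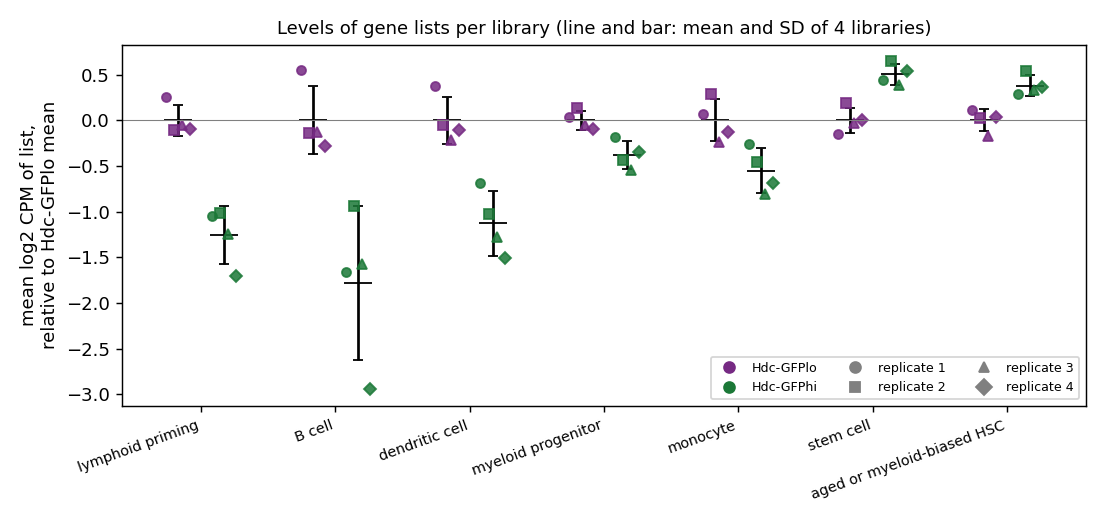
Mean log2 CPM of the members of 7 gene lists in each library, on the y axis, relative to the mean of the 4 Hdc-GFPlo libraries. Symbols give the replicate number, colours the group, and lines with bars the mean and SD of 4 libraries; the lymphoid priming list lies 1.26 lower and the stem cell list 0.50 higher in Hdc-GFPhi, with no overlap between groups.

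Stem cell genes were higher in Hdc-GFPhi as a list. Of 23 measured genes, 2 were called higher, among them Esam (log2 fold change 0.88 ± 0.17, adjusted p = 0.0253), and none was lower. Adjusted over the list alone, 14 were higher, and the median was 0.57 (camera adjusted p = 2.9e-16, and adjusted p = 0.0285 with an estimated correlation). Hlf, a transcription factor of stem cells, had a log2 fold change of 0.44 ± 0.09 (adjusted p just above 0.05) and Gata2, another, had 0.56 ± 0.12 (adjusted p = 0.0593). Hlf was called without Hdc-GFPhi replicate 1 (adjusted p = 0.0463) or Hdc-GFPlo replicate 3 (0.0305), and Gata2 without Hdc-GFPhi replicate 2 (0.0434). The number of called stem cell genes was 1 without Hdc-GFPhi replicate 3, Hdc-GFPlo replicate 1 or Hdc-GFPlo replicate 4, and 4 without Hdc-GFPlo replicate 2 or 3. It was 4 with upper-quartile factors, with no composition factor and with no filter, 8 with the GC and length trend removed, 8 with the split of replicates 1 and 2 against 3 and 4 as a covariate, 12 with DESeq2 and 11 with voom. Hlf and Gata2 were called with that covariate (adjusted p = 0.0243 and 0.0265). Over all alternatives their adjusted p ranged from 0.00155 to 0.826 and from 0.00297 to 0.574. Esam lost its call without Hdc-GFPhi replicates 1, 2 or 3 or Hdc-GFPlo replicates 1 or 4 (adjusted p up to 0.0929). Genes raised in aged or myeloid-biased stem cells were higher as a list, with none of 17 called over all genes and 4 higher when adjusted over the list alone (median 0.54, camera adjusted p = 3.5e-04, and adjusted p = 0.0285 with an estimated correlation). Among them, the integrin Itga2b had a log2 fold change of 0.72 ± 0.18 (adjusted p = 0.0862) and Slamf1 of 0.80 ± 0.24 (adjusted p = 0.185). Itga2b was called without Hdc-GFPlo replicate 4 (adjusted p = 0.0159) and Slamf1 without Hdc-GFPlo replicate 3 (0.0385). With the split of replicates as a covariate, Itga2b (adjusted p = 0.0383), Slamf1 (0.0334) and Fhl1, a LIM domain protein (0.0339, against 0.116 without it), were called. Over all alternatives their adjusted p ranged from 0.00609 to 0.927, 0.0334 to 0.971 and 0.0152 to 0.764. Of 19 megakaryocyte and platelet genes, 1 was called higher (4 higher and 1 lower when adjusted over the list alone), with a median of 0.43 (camera adjusted p = 3.1e-05, but adjusted p = 0.12 with an estimated correlation). Of 12 stromal and endothelial genes, the lipid carrier Apoe rose (log2 fold change 0.68 ± 0.10, adjusted p = 0.00721) and 2 were higher when adjusted over the list alone (median 0.43, camera adjusted p = 0.0053, but adjusted p = 0.132 with an estimated correlation). Among 23 quiescence genes, the cell cycle inhibitor Cdkn1c rose (log2 fold change 0.85 ± 0.15, adjusted p = 0.0188), while the list was not called (2 higher and 1 lower when adjusted over the list alone, median 0.06, camera adjusted p = 0.722). The Cdkn1c call was lost without Hdc-GFPhi replicates 1 or 4 or Hdc-GFPlo replicates 1, 2 or 4 (adjusted p up to 0.088).

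The Hdc transcript was not called between the fractions sorted on its reporter. It averaged 12 ± 2.1 CPM in Hdc-GFPhi and 12.1 ± 1.2 CPM in Hdc-GFPlo (SD, n = 4 each), from 204 to 326 counts per library. The log2 fold change was -0.01 with a 95% interval of -0.39 to 0.38 (adjusted p = 0.995). Whether reads of the reporter transgene are counted as Hdc is not given in the sources used here, so these values need not be of the endogenous transcript alone. None of the 6 measured histamine genes, Hdc among them, was called, over all genes or when adjusted over the list alone, and neither was the list (median 0.05, camera adjusted p = 0.245). Slc18a2, the transporter that loads histamine and other monoamines into vesicles, was at 156 ± 18.2 against 123 ± 13.7 CPM (log2 fold change 0.35 ± 0.12, adjusted p = 0.249). The histamine receptor Hrh2, the organic cation transporter Slc22a3, the histamine methyltransferase Hnmt and the dehydrogenase Aldh7a1 had log2 fold changes between -0.05 and 0.19. Mast cells and basophils are the classic sources of histamine. Of 12 measured mast cell and basophil genes none was called (1 higher when adjusted over the list alone, median -0.17, camera adjusted p = 0.536, with a list mean of 0.06), and the list passed, upward, without Hdc-GFPlo replicate 3 (camera adjusted p = 0.0454) and, on all 8 libraries, with no filter beyond 1 count (0.0271).

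**Figure D3:**
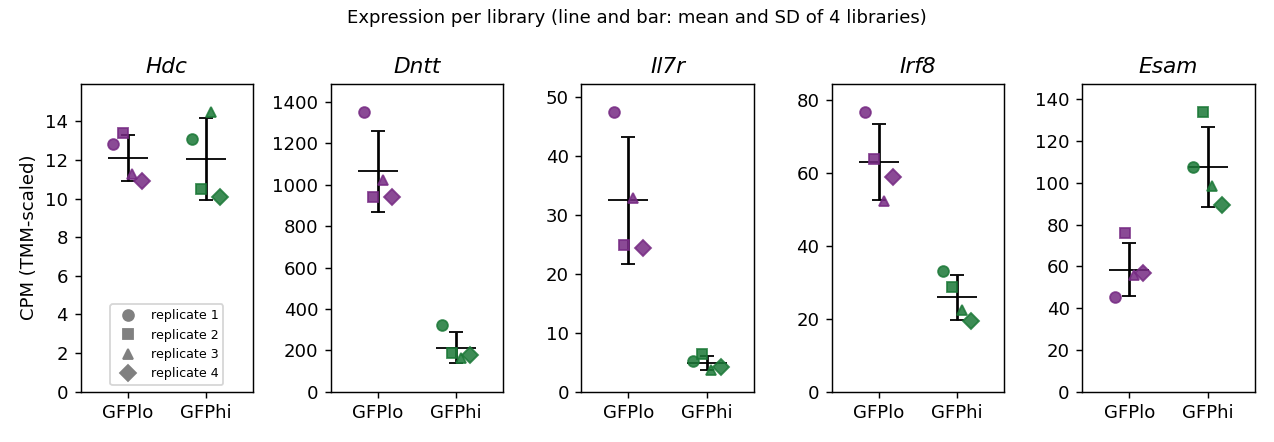
TMM-scaled CPM of 5 genes in each library, from 0 on the y axis, for Hdc-GFPlo and Hdc-GFPhi. Symbols give the replicate number and lines with bars the mean and SD of 4 libraries; Hdc overlaps at about 12 CPM in both groups, Dntt, Il7r and Irf8 are lower and Esam is higher in Hdc-GFPhi.

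Genes of proliferation showed no called member. None of 29 S phase genes passed (median 0.03, camera adjusted p = 0.983, with a list mean of -0.03), nor any of 34 G2/M genes, of which 29 had a log2 fold change above 0 (median 0.12, camera adjusted p = 0.00473, but adjusted p = 0.754 with an estimated correlation). The G2/M call was lost without Hdc-GFPhi replicate 3 (camera adjusted p = 0.294) or Hdc-GFPlo replicate 2 (0.625). The erythroid list (0 of 19 called, median -0.03, camera adjusted p = 0.975) and the glycolysis and hypoxia list (0 of 26 called, 2 higher when adjusted over the list alone, median -0.04 and mean 0.04, camera adjusted p = 0.826) were not called. Interferon response genes (0 of 29 called, median -0.09, camera adjusted p = 0.361) were not called either, but passed as a list without Hdc-GFPhi replicate 1 (0.00374) or Hdc-GFPlo replicate 4 (0.0451). Single members passed in lists that were not called as a whole. Tlr7, a sensor of single-stranded RNA, fell by 1.31 ± 0.17 (adjusted p = 0.00338), and it was the called gene of 26 in the list of Toll-like receptor and inflammatory genes (median -0.06, camera adjusted p = 0.161, but 0.0218 without Hdc-GFPhi replicate 1 and 0.0294 without Hdc-GFPlo replicate 3). Ncf1, a subunit of the phagocyte NADPH oxidase, fell by 0.94 ± 0.11 (adjusted p = 0.00117) among 26 genes of reactive oxygen defence (median -0.06, camera adjusted p = 0.19). H2-Ob, which modulates antigen loading, fell by 0.66 ± 0.09 (adjusted p = 0.00507) among 12 MHC class II genes (median -0.05, camera adjusted p = 0.148, but 0.00516 without Hdc-GFPhi replicate 2). The histone gene Hist1h2bc fell by 0.90 ± 0.18 (adjusted p = 0.0311, lost in 6 of 8 fits with 1 library left out, all but those without Hdc-GFPhi replicate 2 or Hdc-GFPlo replicate 4, and with the GC and length trend removed, 0.0655) among 38 replication histone genes (median 0.03, camera adjusted p = 0.783). Of 27 chemokine, adhesion and homing genes, Ccr9 and Ccr2 were lower and Esam higher (7 lower and 4 higher when adjusted over the list alone, median -0.31, camera adjusted p = 6.2e-04, but adjusted p = 0.413 with an estimated correlation). None of 77 ribosomal protein genes was called (median -0.10, camera adjusted p = 0.0852), but the list passed without Hdc-GFPhi replicate 4 (4.2e-07) or Hdc-GFPlo replicates 1 (0.00501), 2 (0.0147) or 4 (0.00302). It also passed without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together (0.0379). Of 77 oxidative phosphorylation genes, Cox6a2 was lower (median -0.10, camera adjusted p = 0.0142, but adjusted p = 0.877 with an estimated correlation). This list's call was lost without Hdc-GFPhi replicates 2 (camera adjusted p = 0.611) or 3 (0.106), without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3 together (0.0565) and with the GC and length trend removed (0.279). It turned upward, uncalled, without Hdc-GFPlo replicate 3 (0.251).

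Across the 28 lists, camera called 15, of which 10 were lower and 5 higher, and 7 of these calls held with an estimated correlation. The exact permutation test of mean list levels between 4 and 4 libraries, for which the smallest possible two-sided p is 0.0286, reached that value for 9 lists, and none passed after adjustment over the 28 lists (smallest adjusted p = 0.0889). No list could pass this adjustment unless many more than these 9 reached the smallest p, so this outcome does not speak against lists that separate the fractions. The count of 126 genes was 68 without Hdc-GFPhi replicate 3 and 52 without Hdc-GFPlo replicate 1, and the 94 lower genes became 54 and 44. The 32 higher genes became 13, 18, 14, 8 and 15 without Hdc-GFPhi replicates 1, 2 and 3 and Hdc-GFPlo replicates 1 and 4.

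Libraries were similar across all genes, with correlations of log2 CPM of 0.961 to 0.982 within and 0.954 to 0.981 between fractions. The first principal component held 28.2% of the variance and the second 24.5%, and neither separated the fractions by the exact two-sided permutation test (p = 0.114 and p = 0.0857). Hdc-GFPhi replicate 4 lay farthest out on the first and Hdc-GFPlo replicate 3 on the second. A list of immediate-early and stress genes, such as Fos and Egr1, which respond within minutes to handling of cells, was not called between fractions (0 of 23 genes called, median 0.20, camera adjusted p = 0.703), but passed, upward in Hdc-GFPhi, without Hdc-GFPhi replicate 3 (0.0293) or Hdc-GFPlo replicate 1 (0.0168). Its level was 5.78 to 6.41 log2 CPM in replicates 1 and 2 of both fractions and 4.31 to 4.71 in replicates 3 and 4. In a fit with both the fraction and this split, 15 of the 23 genes were higher in replicates 1 and 2. Fos had a log2 difference of 3.74 ± 0.25 and Egr1 of 2.61 ± 0.16. Transcripts of pancreatic digestive enzymes followed the same split. Cel, a lipase of pancreatic juice, had 67, 512, 36 and 71 counts in replicates 3 and 4 of Hdc-GFPhi and of Hdc-GFPlo and 0 in all replicates 1 and 2.

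**Figure D4:**
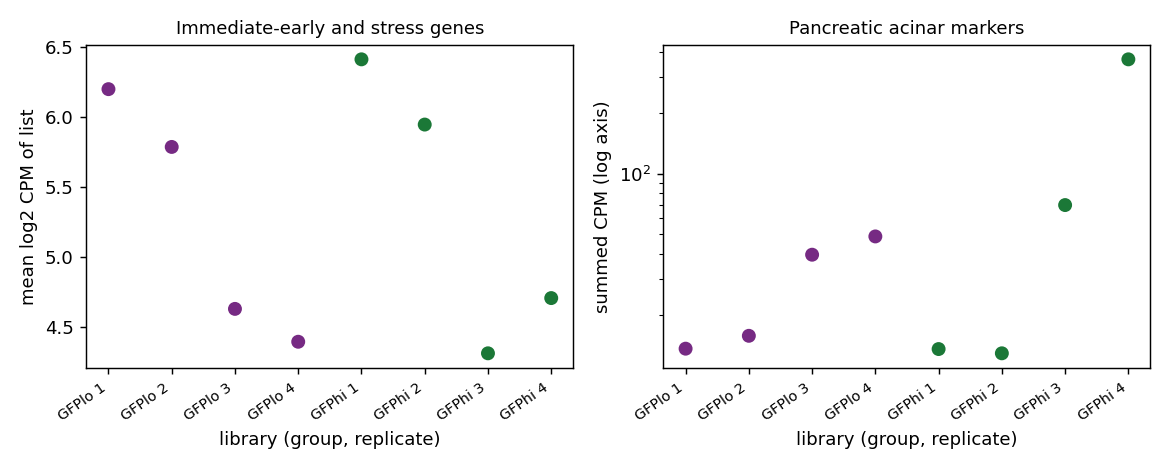
Left, mean log2 CPM of the immediate-early and stress list in each library. Right, summed CPM of 34 pancreatic acinar markers in each library, on a log axis; replicates 3 and 4 of both groups have lower immediate-early levels (4.31 to 4.71) and more acinar transcripts (39.7 to 368 CPM) than replicates 1 and 2.

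Fold changes between the fractions were also computed on each side of this split. The log2 fold change of Dntt was -2.17 in replicates 1 and 2 and -2.52 in replicates 3 and 4, that of Il7r -2.64 and -2.87, that of Irf8 -1.19 and -1.42, that of Apoe 0.85 and 0.50, and that of Hdc -0.15 and 0.15. The median of the lymphoid list was -0.76 and -0.75, that of the B cell list -1.55 and -1.85. That of the dendritic cell list was -0.58 and -0.94, that of the myeloid progenitor list -0.24 and -0.29 and that of the monocyte list -0.47 and -0.75. The stem cell list had 0.51 and 0.50 and the aged stem cell list 0.49 and 0.52. With 2 libraries per fraction, 34 genes passed in replicates 1 and 2 and 19, none of them higher in Hdc-GFPhi, in replicates 3 and 4. Called lower were 4 and 6 lymphoid, 1 and 3 B cell, 1 and 2 dendritic cell, 1 and 1 myeloid progenitor and 0 and 0 monocyte genes, and called higher were 1 and 0 stem cell genes. Il7r and Irf8 passed on both sides, while Dntt missed the threshold in replicates 1 and 2 (adjusted p = 0.0867) and Apoe in replicates 3 and 4 (0.663). Among camera calls, replicates 1 and 2 lost the plasma cell (adjusted p = 0.106) and oxidative phosphorylation lists (0.077) and gained the immediate-early list (0.0351). Replicates 3 and 4 lost the stromal list (0.114) and gained the Toll-like receptor (0.0447), MHC class II (0.0038) and ribosomal protein lists (0.0366). With the split as a covariate over all 8 libraries, 275 genes passed, 191 lower and 84 higher in Hdc-GFPhi, and they included all 126.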

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

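All tests in this part were chosen after the data were seen, except the counts of other splits for genes and for lists by the preset camera test. The 2 tests of the immediate-early genes were chosen after that split was found and before their own values were seen, and the other tests after the results they measure. No other split of the 8 libraries into 4 and 4 called as many genes as the real one. This makes 1 of 35 splits with at least 126 genes, against 46 for the highest other split. No smaller share is possible with 35 splits. Every other split also mixes libraries of both fractions, so a difference between the fractions adds to its spread and can lower its count. These splits therefore cannot exclude chance for that count. The split with 46 genes set replicates 1 and 2 of both fractions against replicates 3 and 4. For the 15 gene lists called by camera at the preset correlation, chance cannot be excluded, since 8 of 35 splits called as many and the highest other split called 22. With an estimated correlation the real split called 7 lists, 1 of 35 splits called as many, and the highest other split called 2. The limits given for the gene count hold here too.

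The lower level of lymphoid and B lineage genes in Hdc-GFPhi was weighed against 3 technical explanations. With the trend on GC content and transcript length removed, 11 of the 12 lymphoid genes called lower stayed called and the list median was -0.75, against -0.74 before, which argues against that trend as the whole cause. Mature B cells that pass the lineage gate into Hdc-GFPlo would bring their abundant MHC class II transcripts, but the summed CPM of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 differed by -0.123 CPM (Hdc-GFPlo minus Hdc-GFPhi, SE 20.5), against a gap of 297 CPM for the B cell list. Committed B cell precursors, which have little MHC class II, would leave level the myeloid genes that they lack. Of 43 myeloid progenitor and monocyte genes outside the lymphoid and B cell lists, 6 were called lower in Hdc-GFPhi. These 6 are the genes already called in those myeloid lists. Absence from the lymphoid and B cell lists does not show that B cell precursors lack them. This count therefore cannot exclude such cells for the myeloid genes, and for the B lineage genes they also stay open. A difference in the mix of progenitors between the gates and a change within each cell were not tested and both stay open.

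The similar Hdc counts in fractions sorted by the reporter were weighed against 2 technical explanations. Reads of the reporter transgene counted as Hdc would be another, which was not tested and stays open. Depth is not the limit, since the upper end of the 95% interval of the log2 fold change is 0.38, below a 2-fold difference. An exchange of single libraries between the fractions would place at least 1 library of each in the other's range, but the lowest Hdc-GFPlo library lies 0.92 above the highest Hdc-GFPhi library in mean log2 CPM of the lymphoid list. An exchange of the whole fractions is not excluded, and how the reporter's fluorescence relates to the Hdc transcript was not tested, because GFP is not analysed here.

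The split of replicates 1 and 2 against replicates 3 and 4 was found in the data, and no label gives a day or a batch. With the GC and length trend removed, the gap in the immediate-early list level was 1.5 log2 CPM, against 1.57 before, which argues against that trend. In a fit without the fraction, the split called 32 genes outside the list, of which 8 are acinar markers and 24 are not. The highest other split that cuts across the fractions called 1. A shared difference in handling between the replicates is a candidate cause of the immediate-early change. The count cannot tell handling from another difference shared by these libraries. In the fit with both the fraction and the split, 65 genes were higher and 51 lower in replicates 1 and 2. Besides the immediate-early list, the quiescence list (5 of 23 genes higher) passed camera with an estimated correlation (adjusted p = 0.0374). Interferon response genes (4 of 29 higher) did not (0.135). At the preset correlation further lists passed in both directions, such as B cell genes higher (5.3e-06) and oxidative phosphorylation genes lower (1.4e-13) in replicates 1 and 2. Material of pancreatic acinar cells, which a bone marrow sort would not hold, is a second candidate for the enzyme transcripts. Of 34 acinar markers, 22 had more counts in each library of replicates 3 and 4 than in any of replicates 1 and 2 (chance gives 1.43%). Cela2a had 1399 and Ctrb1 808 counts in Hdc-GFPhi replicate 4. That library had the highest summed level (368 CPM, against 39.7 to 69.9 in the other libraries of replicates 3 and 4). Cela1 also separated, but had 164 to 220 counts in replicates 1 and 2. Correlations across markers were 0.782 to 0.938. The share of markers and the lowest correlation fell short of the bounds of 2/3 of markers and a correlation of 0.8 set for that test. Markers with almost no counts, such as Rbpjl and Prss3 with at most 1 in any library, lower that share. This candidate therefore stays undecided, and no biological explanation of the split was tested.

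In 306 groups of 4 values examined with Dixon's test, 21 held a library set apart from the other 3, where about 1 in 20 is given by chance. The test weighs a gap against the range of the 4 values, so the gap itself can be small. Tacc3, for example, was at 7.15 against 7.34 to 7.36. The Lef1 value below stands for 0 counts and is set by the prior count, and the plasma cell list holds Igj. In log2 CPM, the library apart within Hdc-GFPhi was replicate 3 for Fscn1 (3.34), replicate 4 for Igll1 (-2.12), Vpreb1 (-0.39) and Lef1 (-3.37), replicate 1 for Fhl1 (3.29) and Ifi27l2a (3.06), and replicate 2 for Egln1 (6.27). Within Hdc-GFPlo it was replicate 3 for Col4a1 (5.17), Eng (6.55), Rpl5 (4.53) and Uqcrfs1 (8.06), replicate 2 for Tacc3 (7.15) and Cybb (5.37), replicate 1 for Usp18 (6.30) and Igj (-0.16), and replicate 4 for Hist1h2bc (5.03). Among mean list levels it was Hdc-GFPlo replicate 1 for lymphoid priming (7.19) and plasma cell genes (3.01), and Hdc-GFPlo replicate 3 for reactive oxygen defence (6.86) and ribosomal protein genes (6.21). Among library totals it was Hdc-GFPhi replicate 2, with 21041170 counts.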

How the results depend on the processing

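Chosen after seeing the data were the GC and length trend removal, the covariate and separate fits for replicates 1 and 2 against 3 and 4, the fit without Hdc-GFPhi replicate 4 and Hdc-GFPlo replicate 3, thinning and the other settings of the principal components. The 126 genes (32 higher, 94 lower) became 224 (84 higher) with a replicate block, and 10 stem cell genes were then called higher. Same-numbered libraries had r of residual profiles of 0.257, 0.347, 0.0755 and 0.1, so not every pair passed the required 0.1: replicates 1 and 2 were closest to their own number, and Hdc-GFPhi replicates 3 and 4 to Hdc-GFPlo replicates 4 and 3. They became 226 (81 higher, 145 lower) with the GC and length trend removed, 275 (84 and 191) with the split of replicates as a covariate, 410 (163 and 247) with DESeq2 and 278 (99 and 179) with voom, and the cause was not tested. All 126 were among the 410 and the 275, and 124 among the 278. With 2 libraries per fraction, replicates 1 and 2 alone gave 34 (7 and 27) and replicates 3 and 4 alone 19 (0 and 19, with 660 genes at an unadjusted p under 0.05). Leaving out 1 library gave 52 (without Hdc-GFPlo replicate 1) to 146 genes (without Hdc-GFPlo replicate 3), 8 to 41 higher and 44 to 105 lower, at the same libraries. Other scalings, filters, thinning and no robust estimation gave 126 to 147 genes, and the fit without both extreme libraries 109. The count of lists, 15, was 7 with an estimated correlation, 9 by fry and 14 to 17, not always the same lists, with 1 library left out. With 1 library left out, the oxidative phosphorylation list ranged from an adjusted p of 2.4e-07 (without Hdc-GFPhi replicate 4) to 0.611 (without Hdc-GFPhi replicate 2) and turned upward without Hdc-GFPlo replicate 3 (0.251), and it reached 0.877 with an estimated correlation. No list passed on library levels under any scaling or filter tried. The smallest possible exact p lets none pass unless many lists reach it at once, so that outcome was close to fixed. The exact permutation p was 0.114 to 0.143 for the first and 0.0571 to 0.0857 for the second principal component. No called named gene changed direction in any alternative. Thinning to the smallest library gave 137 genes, so the count did not fall with depth over that range. Small changes can be missed, since 26.5% of simulated changes of 0.5 on the log2 scale were recovered.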

Other observations

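The genes in this part were chosen after their values were seen. Of the 126 called genes, 93 were in none of the fixed lists. Among those higher in Hdc-GFPhi were Prdm16, a transcription factor that maintains stem cells (log2 fold change 0.60 ± 0.12 SE, adjusted p = 0.0403), the transcription factor Sox6 (0.94 ± 0.15, adjusted p = 0.00911) and the imprinted adaptor Grb10 (0.98 ± 0.14, adjusted p = 0.00572). Among those lower were Cd48, a surface protein absent from most long-term stem cells (-0.71 ± 0.13, adjusted p = 0.0228), Id3, an inhibitor of E proteins (-2.63 ± 0.37, adjusted p = 0.00507), Tyrobp, a signalling adaptor of myeloid and NK cells (-0.77 ± 0.11, adjusted p = 0.00507), and Cd93, a surface protein of early progenitors (-0.51 ± 0.10, adjusted p = 0.0322).

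Transcripts of basophils and mast cells were uneven between libraries. Prss34, a basophil protease, had 0, 777, 494 and 1069 counts in Hdc-GFPhi replicates 1 to 4 and 0, 0, 1120 and 3 in Hdc-GFPlo replicates 1 to 4. Ms4a2, a chain of the IgE receptor, had 5, 6, 45 and 62 against 0, 0, 5 and 1 counts, and Mcpt8, another basophil protease, 43, 79, 88 and 158 against 40, 31, 266 and 47. The mast cell proteases Cma1 and Tpsb2 reached 70 and 84 counts in Hdc-GFPhi replicate 3 and at most 1 and 0 in the Hdc-GFPlo libraries.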
